A study of Homo sapiens with 9 samples.

How the data were processed

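Gene expression was measured by stranded RNA sequencing of polyadenylated RNA in 9 samples of PLC/PRF/5, a human hepatoma cell line, made to express the tyrosine kinase YES stably as wild type (4 samples) or with the gatekeeper mutation T348I (5 samples). All 9 samples had received 100 nM dasatinib, per the labels. RNA was extracted with TRIzol and a Qiagen column and libraries were made with a stranded KAPA kit for polyA RNA, per the labels' protocols.

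The deposited files hold raw counts of reads per gene, 1 file per sample, which the authors made with CASAVA 1.8.2, Trimmomatic 0.35 and STAR 2.5.1b on build GRCh38, per the submitters' processing notes. The annotation release and the filters are not given in the sources used here. Each file gives counts without regard to strand and counts for each strand, in the layout that STAR writes. The counts of column 4 were used, which hold the sense strand of this kind of kit. Gene reads of the opposite strand came to 5.48% to 5.91% of those of the sense strand. The rows that name no gene (unmapped, multimapped, no feature and ambiguous reads) held 22.2% to 29.8% of the reads of a file and were left out of library sizes and tests. Reads that map to several places therefore count for no gene, which lowers genes with near-identical copies elsewhere in the genome.

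Of the 58219 gene identifiers, 57437 were given a symbol from a table of gene names. GENCODE release 29 on GRCh38 held 57881 of them, 55008 with the same version number, and coordinates are printed only for genes with the same version number. Gene lists were matched by current symbol and, where that failed, by the GENCODE release 29 name.

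The labels give the group of every sample. Sample titles spell the drug as dasatinib (3 wild-type and 3 T348I samples) or as Dasa (1 wild-type and 2 T348I samples), each with its own numbering from 1. The labels do not say that the spelling marks a batch. It was entered as a term in the model and the 2 sets are called the dasatinib set and the Dasa set. Nothing in the labels says that samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No pair of samples within a group and set was a duplicate: chi-square per gene between their counts lay between 1.49 and 3.09, above the value of about 1 that sampling noise alone gives.

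Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F-test in a model with set and group, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold minimum. Log2 fold changes are T348I over wild type. Standard errors were derived from the fold and the F statistic. Expression levels are CPM, counts scaled to a common depth with the TMM-adjusted library sizes. A second model added the interaction of set and group, which tests whether the fold differs between the sets.

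Before the data were examined, 34 gene lists were fixed, and 32 of them had at least 3 tested genes. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way and makes no comparison with other genes. For YES1 an exact two-sided permutation test of log2 CPM was added. Named genes follow a rule set at the same time: YES1 and the other tested genes of the Src family list, the 12 genes with the largest fold in each direction among those called with a mean log2 CPM of at least 1 and the same sign in both sets, and up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

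Where wild-type samples held no read of a gene, the fold is a lower bound against a floor of 3 reads over the group. Where they held few, the ratio of reads carries a 95% exact interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Depth was 10381142 to 15799059 gene reads per sample.

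The script was tested on simulated data for the comparison of T348I with wild type. These data had the real genes and depths, and a spread taken from the trend over genes, not from each gene. Changes were placed only in genes with a mean of at least 10 reads per sample. Of 50 genes changed at each size, the script recovered 52% at 1.2-fold, 86% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 14432 genes tested and 10 false calls among 174. Far fewer genes were changed than were called in the real data, so these rates may not carry over. A list raised by 1.3-fold was found and 0 of the other lists were called. The simulated genes varied independently, so this cannot show how often the list test calls wrongly among correlated genes.

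Alternatives were other scalings (DESeq2-style size factors and upper quartile), other filters (none, and a mean CPM of at least 1), DESeq2 1.42.0, limma-voom, a stricter threshold, a 1.5-fold minimum, no set term, a replicate block, the dasatinib set alone, and each sample left out in turn. Counts without regard to strand, and all alternatives for the interaction, were added after the data had been seen.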

Results

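The data are RNA sequencing counts from 9 samples of PLC/PRF/5, a human hepatocellular carcinoma line, that stably expressed YES, a tyrosine kinase of the Src family encoded by YES1. In 4 samples YES was wild type and in 5 it carried T348I, a change at the gatekeeper position of the kinase's drug pocket. Gatekeeper mutations are known to reduce binding of dasatinib, an inhibitor of Src family and ABL kinases. All samples had received 100 nM dasatinib, and no untreated sample was analysed here, so each value compares T348I with wild type in the presence of the drug. Wild-type samples held 10464731 to 14118614 reads in genes and T348I samples 10381142 to 15799059. Titles spell the drug in 2 ways, and the dasatinib set (3 wild type, 3 T348I) and the Dasa set (1 wild type, 2 T348I) stood apart: mitochondrial transcripts took 5.6% to 7.38% of gene reads in the first and 13.2% to 14.5% in the second, and 8568 genes differed between the sets in the edgeR test.

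YES1 transcript itself was higher in all 5 T348I samples than in any of the 4 wild-type samples. YES1 (ENSG00000176105.13, a protein-coding gene on the minus strand of chromosome 18, 721588 to 812546 in GRCh38) stood at 354 ± 13.2 CPM (SD, n = 4) in wild-type samples and 749 ± 233 CPM (SD, n = 5) in T348I samples. The log2 fold change was 0.95 with a standard error of 0.0872 (edgeR adjusted p = 4.84e-08). The exact two-sided permutation test of the group labels gave p = 0.0079, the smallest that 126 splits allow. T348I samples held 553 to 605 CPM in the dasatinib set and 974 and 1030 CPM in the Dasa set, a fold over wild type of 1.66 and 2.72. The difference of 0.71 between the log2 folds of the sets passed the edgeR interaction test (adjusted p = 2.3e-09), which takes the 1 wild-type sample of the Dasa set to vary like samples of the other groups. Both groups carried an introduced YES1, and a count per gene cannot tell introduced from endogenous transcript or mutant from wild type.

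**Figure D1:**
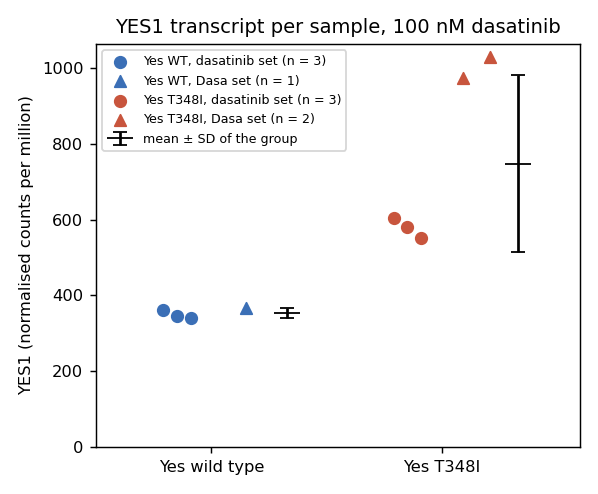
YES1 in normalised counts (CPM, y axis) for each sample, by group (x axis) and set (circles, dasatinib set; triangles, Dasa set); black bars are the group mean and SD. The 5 T348I samples lie between 553 and 1030 CPM and the 4 wild-type samples between 341 and 368 CPM.

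Other Src family kinases and their regulators changed in both directions. Of the 9 tested members of this list, 2 rose (YES1, and PTPN1, a tyrosine phosphatase, by 0.24 on the log2 scale, or 0.15 without wild-type Dasa replicate 1) and 3 fell. SRC fell by 0.31 (edgeR adjusted p = 0.000111), MATK, a kinase related to CSK, fell by 0.78 (edgeR adjusted p = 0.0157) and PTPRA, a receptor phosphatase, fell by 0.15 (edgeR adjusted p = 0.0332). FYN (-0.10), FRK (-0.16), LYN (0.0024) and CSK (0.08) did not pass the test. Adjusted over the list alone, the counts were the same. The list as a whole was not called (camera adjusted p = 0.944), and its median of -0.10 and its test direction, upward, differ in sign. SRC (-0.35), MATK (-0.89) and PTPRA (-0.13) were not called without the set term, and DESeq2 called neither MATK (-0.77) nor PTPRA (-0.15). PTPRA also lost its call with the replicate block (-0.16), and without wild-type dasatinib replicates 1 (-0.13) or 2 (-0.12), or T348I dasatinib replicates 1 (-0.12) or 2 (-0.14) or Dasa replicate 1 (-0.14), and MATK lost its call without wild-type dasatinib replicate 3 (-0.71) or T348I dasatinib replicate 2 (-0.62). FRK gained a call without wild-type dasatinib replicate 2 (-0.23) and with no filter (-0.17), and its log2 fold was -0.0079 without wild-type Dasa replicate 1. CSK gained a call without T348I dasatinib replicate 1 (0.11).

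The strongest differences were genes almost silent in wild-type samples and expressed in T348I samples. MMP1, an interstitial collagenase (chromosome 11, 102789920 to 102798160 in GRCh38), rose from 0.334 ± 0.0718 CPM (SD, n = 4) to 228 ± 29.8 CPM (SD, n = 5), a log2 fold change of 9.41 with a standard error of 0.089 (edgeR adjusted p = 1.15e-23). KRT6A, a keratin of stratified and stressed epithelium (chromosome 12, 52487174 to 52493257), had 0 reads in the 4 wild-type samples and 588 in T348I samples, at least 160-fold higher against a floor of 3 reads over the group. PPBP, a platelet chemokine precursor, rose by 6.92 on the log2 scale.

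For genes with 1 to 4 wild-type reads the ratio of pooled CPM is given with its 95% counting interval. It was 595 (164 to 4920) for THBD, which encodes the anticoagulant receptor thrombomodulin, and 332 (59.2 to 13100) for the cytokine gene IL24. FAM83A, whose product is linked to EGFR signalling, had a ratio of 359 (64.1 to 14200), and BCL2A1, an anti-apoptotic BCL2 relative, 242 (66.8 to 2010). The ratios were 117 (32 to 967) for the neurotensin receptor gene NTSR1, 103 (39.8 to 378) for the anion exchanger gene SLC26A4, 100 (27.4 to 832) for the ectonucleotidase gene ENTPD3 and 91.4 (35.4 to 337) for the tight junction gene CLDN18. The genes named here for the largest rise all had the same sign in both sets, which the rule for naming them requires.

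The largest falls were smaller, and several were in liver genes. G6PC1, the glucose-6-phosphatase that releases glucose from liver (chromosome 17, 42900797 to 42913369), fell by 2.23 on the log2 scale with a standard error of 0.141, from 139 ± 39.3 CPM (SD, n = 4) to 29.9 ± 6.07 CPM (SD, n = 5) (edgeR adjusted p = 2.01e-10). SERPINF2, the plasma plasmin inhibitor, fell by 2.07, the scaffold gene PDZK1 by 2.04 and the manganese exporter gene SLC30A10 by 2.01, or by 1.24 without wild-type Dasa replicate 1. BAAT, which conjugates bile acids to amino acids, fell by 1.97. APOA1, the main protein of high-density lipoprotein, fell by 1.67. The vesicle trafficking gene RAB11FIP4 fell by 1.92, the sugar transporter gene SLC5A9 by 1.70 and the zinc transporter gene SLC39A5 by 1.66. AMN and ASB5 each fell by 1.61. The edgeR adjusted p of these genes lay between 5.14e-15 (RAB11FIP4) and 7.29e-07 (SLC30A10). Within the dasatinib set the log2 folds of SLC5A9 and AMN were -1.16 and -1.21. Wild-type Dasa replicate 1 held more of both, at 26.1 and 39.1 CPM, than any other wild-type sample.

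**Figure D2:**
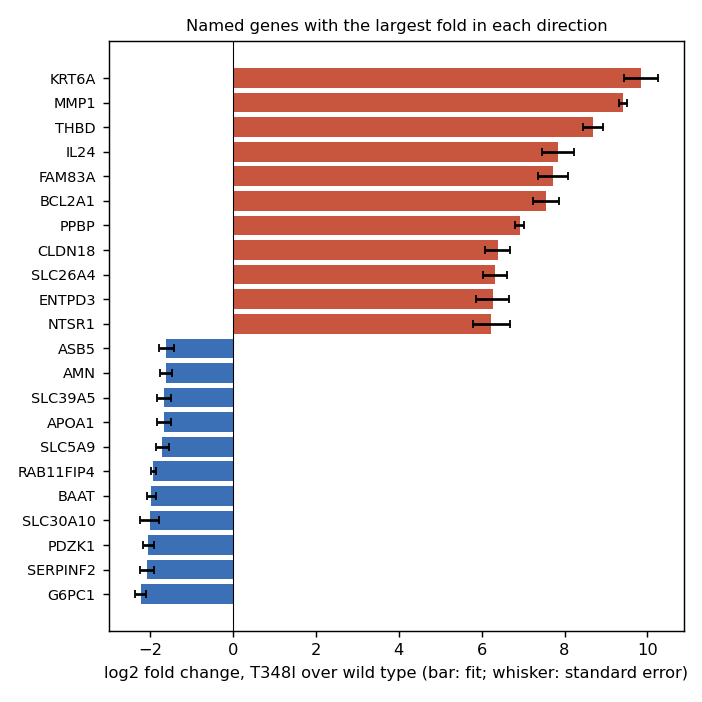
Log2 fold change (x axis, T348I over wild type) of the genes named above among those with the largest change in each direction; bars are the edgeR fit over 9 samples and whiskers its standard error. Rises reach 6.92 for PPBP and 9.41 for MMP1, above which lies KRT6A, whose bar rests on 0 wild-type reads and is no measured fold, and falls reach -2.23 for G6PC1.

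Over all genes, 6212 of 14617 tested passed the edgeR threshold, 3029 higher and 3183 lower in T348I samples. Large changes were mostly rises: of 521 genes that changed at least 2-fold, 355 rose and 166 fell, and of 148 that changed at least 4-fold, 142 rose and 6 fell. Requiring a 1.5-fold change left 1366 genes, 708 higher and 658 lower. Without the set term 2350 genes were called, 1234 higher and 1116 lower, all of them among the 6212.

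Targets of the ERK pathway rose without exception. All 15 tested genes of this list were higher in T348I samples, with a median log2 fold change of 1.10 (camera adjusted p = 4.54e-54, and 0.0118 with an estimated correlation). DUSP5, an ERK phosphatase, rose by 3.01, SPRY4, a feedback inhibitor of receptor signalling, by 2.25, FOSL1, a subunit of the AP-1 transcription factor, by 3.72 and IER3 by 1.91. Among immediate early genes, which respond to growth factor signals within minutes, 14 of 17 rose and 2 fell, with a median of 0.61 (camera adjusted p = 3.27e-16, and 0.0175 with an estimated correlation). EGR1 rose by 2.30 and JUNB by 1.34. Of 9 EGFR ligands and related receptors, 6 rose and 3 fell, with a median of 0.60 (camera adjusted p = 3.12e-06, and 0.0175 with an estimated correlation). The EGFR ligand genes HBEGF, AREG and EREG rose by 2.08, 1.04 and 0.92, and the receptor kinase gene AXL by 1.38. Adjusted over the list alone, the counts of these lists were the same.

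Targets of the transcriptional coactivators YAP and TAZ and the focal adhesion list were also higher. Of 19 YAP/TAZ targets, 15 rose and 1 fell, with a median of 0.86 (camera adjusted p = 2.37e-16, and 0.0339 with an estimated correlation). CCN1 and CCN2, which encode matricellular proteins, rose by 2.94 and 1.16, and NT5E, an ectonucleotidase, by 2.21. Of 27 focal adhesion genes, 15 rose and 2 fell, with a median of 0.21 (camera adjusted p = 4.64e-10, and 0.0364 with an estimated correlation). The integrin gene ITGA2 rose by 2.15, and the adaptor genes PXN and ZYX by 1.49 and 0.92. Of 12 TGF-beta targets, 8 rose, 9 adjusted over the list alone, with a median of 0.31, or 0.47 without wild-type dasatinib replicate 1 (camera adjusted p = 2.55e-16, and 0.00317 with an estimated correlation). Besides JUNB, ID1, a repressor of differentiation, rose by 0.59. Of 18 targets of the transcription factor SRF and genes of the actin cytoskeleton, 14 rose and 1 fell, with a median of 0.36. This call (camera adjusted p = 4.88e-06) was lost with an estimated correlation (adjusted p = 0.202). The actin crosslinker gene FLNA rose by 0.67 and ACTB, beta-actin, by 0.68. The counts of the YAP/TAZ, focal adhesion and SRF lists were the same adjusted over the list alone.

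The lists of STAT3 targets, interferon response and NF-kB targets were higher as well. Of 11 STAT3 targets and acute phase genes, 9 rose and 2 fell, with a median of 0.93 (camera adjusted p = 3.5e-20, and 0.00188 with an estimated correlation), the same counts adjusted over the list alone. SOCS3, a feedback inhibitor of cytokine receptors, rose by 3.71, from 5.3 ± 1.2 CPM (SD, n = 4) to 80.2 ± 36.3 CPM (SD, n = 5). LBP, an acute phase protein gene, rose by 3.87, the oncostatin M receptor gene OSMR by 1.47 and STAT3 itself by 0.93. Of 16 interferon response genes, 15 rose, 16 adjusted over the list alone, with a median of 1.48 (camera adjusted p = 1.26e-18, and 0.0364 with an estimated correlation). The antiviral genes MX1, IFIT1 and OAS3 rose by 4.33, 2.98 and 1.09, and IFI6 by 2.27. Of 16 NF-kB targets and chemokines, 10 rose, the same adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.53e-12, and 0.0302 with an estimated correlation). LIF, an interleukin-6 family cytokine gene, rose by 5.20, from 0.996 ± 0.487 CPM (SD, n = 4) to 40.9 ± 12.5 CPM (SD, n = 5), the adhesion receptor gene ICAM1 by 1.11 and the neutrophil chemokine gene CXCL8 by 0.81.

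Hepatocyte markers fell. Of 27 tested, 20 fell and 1 rose, the same adjusted over the list alone, with a median of -0.55. The call (camera adjusted p = 2.02e-06) was lost with an estimated correlation (adjusted p = 0.442). Besides G6PC1 and APOA1, TF, the transferrin gene, fell by 0.76, from 639 ± 30.7 CPM (SD, n = 4) to 374 ± 51 CPM (SD, n = 5), and the membrane protein gene TM4SF4 fell by 0.92. ASGR2, a subunit gene of the asialoglycoprotein receptor, was the 1 marker that rose, by 0.40, and is named after its value was seen. The median was -0.29 without wild-type Dasa replicate 1 and -0.29 in the dasatinib set alone, where the edgeR test called 15 markers lower and 6 higher. TM4SF4 was not called without the set term (-0.98).

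Biliary and progenitor markers changed in both directions, with 5 of 11 higher and 4 lower (camera adjusted p = 0.347, median -0.01, test direction upward). The biliary keratin gene KRT19 rose by 1.66 and the hyaluronan receptor gene CD44 by 2.95, while the surface glycoprotein gene CD24 fell by 0.73. Of 12 epithelial markers, 4 rose, 5 adjusted over the list alone, and 5 fell (camera adjusted p = 0.656, and adjusted p = 0.721 with an estimated correlation, median -0.12, test direction upward). The simple epithelial keratin genes KRT18 and KRT8 rose by 1.22 and 0.94, and CDH1, E-cadherin, fell by 0.83. At the preset correlation this list was called in the dasatinib set alone and without wild-type Dasa replicate 1, with a median of -0.09 in each and a test direction upward. Of 10 mesenchymal markers, 4 rose and 3 fell (camera adjusted p = 0.347). VIM, vimentin, rose by 0.83 and CDH2, N-cadherin, fell by 0.62. Counts of the biliary and mesenchymal lists were the same adjusted over the list alone. Fry, which makes no comparison with other genes, called the biliary (adjusted p = 0.000752), epithelial (adjusted p = 0.0446) and mesenchymal (adjusted p = 0.000486) lists. Values of KRT6A, KRT8, KRT18, CD24 and ACTB are uncertain, because near-identical genes or pseudogenes share reads with them.

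Genes of cell division and growth were slightly higher. Of 23 G2/M genes, 17 rose and 1 fell, the same adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.00137, and adjusted p = 0.239 with an estimated correlation). The mitotic genes PLK1 and CDC20 rose by 0.38 and 0.51. Of 24 G1/S genes, 14 rose and 2 fell, 15 and 3 adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0434, and adjusted p = 0.442 with an estimated correlation). RRM2, a ribonucleotide reductase subunit gene, rose by 0.51 and the replication factor gene MCM10 by 0.31. The G1/S call was lost with upper quartile scaling (median 0.13), with the replicate block (median 0.14) and in the dasatinib set alone (median 0.14). It was also lost without wild-type Dasa replicate 1, T348I dasatinib replicate 2 or 3, or T348I Dasa replicate 2 (median 0.14 in each). Of 20 MYC targets and ribosome biogenesis genes, 18 rose, 19 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 2.02e-06, and adjusted p = 0.3 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, rose by 0.83 and MYBBP1A by 0.38, the latter not called without the set term (log2 fold 0.47). Of 21 genes of hypoxia and glycolysis, 13 rose, 14 adjusted over the list alone, and 4 fell, with a median of 0.23 (camera adjusted p = 7.7e-06, and adjusted p = 0.154 with an estimated correlation). The stress-responsive gene NDRG1 rose by 2.76 and the transcription factor gene BHLHE40 by 1.47.

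Of 13 transcripts of the mitochondrial genome, 9 rose, 10 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.0434, and adjusted p = 0.637 with an estimated correlation). MT-ND4, a complex I subunit gene, rose by 0.27 and was not called without the set term (log2 fold 0.48). In the dasatinib set all 13 were called higher, and the mitochondrial share of reads was 6.16% to 7.38% in T348I samples and 5.6% to 6.0% in wild-type samples. In the Dasa set the shares were 14.5% and 13.2% in T348I samples and 14.4% in the wild-type sample. The list's call was lost with fry (adjusted p = 0.0664). Camera did not call it with upper quartile scaling (median 0.21) or without the set term (median 0.37). The camera call was also lost without wild-type dasatinib replicate 1 (median 0.17) or 2 (median 0.19). The same held without T348I dasatinib replicate 1 (median 0.15) or 2 (median 0.21), or T348I Dasa replicate 1 (median 0.22).

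Among genes of lipid metabolism, cholesterol synthesis genes were lower: of 22, 13 fell and 3 rose, with a median of -0.16 (camera adjusted p = 0.0434, and adjusted p = 0.588 with an estimated correlation). Mevalonate kinase, MVK, fell by 0.71 and the sterol sensor gene INSIG1 by 0.73. The list's call was lost without the set term (-0.25), with the replicate block (-0.15), in the dasatinib set alone (-0.11), and without wild-type Dasa replicate 1 (-0.11), T348I dasatinib replicate 1 (-0.16) or T348I Dasa replicate 1 (-0.15) or 2 (-0.14). INSIG1 was not called without the set term (-0.84). Of 14 fatty acid synthesis genes, 5 rose and 4 fell (camera adjusted p = 0.763, median -0.01, test direction downward). Of 15 targets of the oxidative stress factor NRF2, 6 fell and 2 rose, with a median of -0.07, or -0.10 without wild-type dasatinib replicate 1 and -0.11 without T348I dasatinib replicate 2 (camera adjusted p = 0.0133, and adjusted p = 0.143 with an estimated correlation). The aldo-keto reductase genes AKR1C1 and AKR1C2 fell to 0.421 and 0.435 of their wild-type level, values that are uncertain because the genes are near-identical. Counts of these 3 lists were the same adjusted over the list alone.

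Camera called none of the remaining pathway lists over all samples. Fry, which makes no comparison with other genes, called the dasatinib targets (adjusted p = 0.000186), p53 (0.000179) and aryl hydrocarbon receptor (0.000457) lists. It also called the Wnt (0.0118) and ATF4 (0.0411) lists, but not the Notch (0.676) and histone (0.242) lists. Of 12 dasatinib targets outside the Src family, 6 rose and 2 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.056), with the ephrin receptor gene EPHA2 higher by 1.66 and the kinase gene SIK2 lower (-0.43). Camera called that list in the dasatinib set alone (median 0.15) and without wild-type dasatinib replicate 3 (0.22) or wild-type Dasa replicate 1 (0.15). It also did so with counts made without regard to strand (0.22), an alternative chosen after seeing the data. With an estimated correlation over all samples its adjusted p was 0.239. Of 15 p53 targets and growth arrest genes, 4 rose and 8 fell, 4 and 9 adjusted over the list alone (camera adjusted p = 0.347, median -0.16, test direction upward). CDKN1A, the cell cycle inhibitor p21, rose by 2.30 and the secreted stress factor gene GDF15 by 0.80. TP53INP1 was lower, at 12 to 22.2 CPM in T348I samples and 25.6 to 27.9 CPM in wild-type samples. Of 22 genes of ATF4 and the unfolded protein response, 9 rose and 8 fell (camera adjusted p = 0.763). Of 5 targets of the aryl hydrocarbon receptor, 1 rose and 1, CYP1A1, fell by 0.69 (camera adjusted p = 0.347), and CYP1A1 was not called without the set term (-0.79). Of 11 Wnt targets, 1 rose and 4 fell (camera adjusted p = 0.364), and of 8 Notch targets 2 rose and 2 fell (camera adjusted p = 0.996, median -0.10, test direction upward). Counts of these 4 lists were the same adjusted over the list alone. Of 12 replication-dependent histone genes, 2 rose, neither of them adjusted over the list alone (camera adjusted p = 0.609).

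Markers of other cell types were mostly below the filter. Of 14 immune markers 3 were tested and 1 rose (camera adjusted p = 0.347): CD79A, a B cell receptor component gene, with 4 reads in wild-type and 88 in T348I samples. LYZ, lysozyme, was abundant in both groups, at 1160 ± 134 CPM (SD, n = 4) in wild-type and 1140 ± 303 CPM (SD, n = 5) in T348I samples. It did not pass the test (log2 fold 0.03), except in the dasatinib set alone and without wild-type Dasa replicate 1 (log2 fold 0.16 in each). Of 12 fibroblast and stellate cell markers 3 were tested, of which COL1A1 and THY1 rose and LRAT fell (camera adjusted p = 0.721). All 3 lay below 6 CPM in each group's mean. Without the set term COL1A1 (log2 fold 0.67) and THY1 (log2 fold 0.98) were not called. THY1 was not called without T348I dasatinib replicate 3 (log2 fold 0.90). LRAT was called neither by DESeq2 (-0.76) nor with the replicate block (-0.74). Of 10 endothelial markers 2 were tested, too few for a list test, and LYVE1 rose, with 6 reads in wild-type and 66 in T348I samples. None of the 7 red cell markers was tested. The counts were the same adjusted over the list alone. Fry called the immune (adjusted p = 0.0125) and fibroblast (adjusted p = 0.00414) lists.

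In all, camera called 18 of 32 lists, 15 upward and 3 downward, and 9 of these also with an estimated correlation, all upward. Over 99 other splits of the 9 samples into 4 and 5, the preset test called a median of 12 lists.

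**Figure D3:**
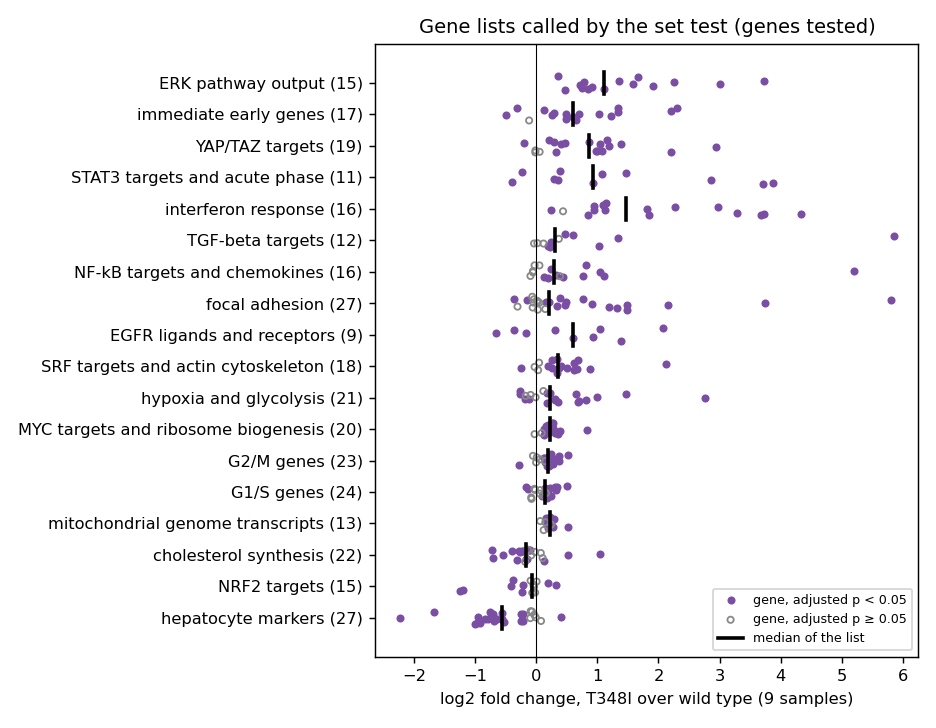
Log2 fold change (x axis, T348I over wild type, edgeR fit over 9 samples) of each tested gene in the 18 lists that camera called at the preset correlation, 1 row per list with the number of tested genes; filled points passed the edgeR threshold, open points did not, and black bars are medians. Medians run from -0.55 for hepatocyte markers to 1.48 for interferon response genes, and all 15 ERK pathway genes lie above 0.

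The same comparison was made within each set. The dasatinib set alone called 5041 genes in edgeR, 2619 higher and 2422 lower. Of 5031 called there and measured in the Dasa set, 4788 had the same sign in the Dasa set, 95.2% (exact 95% interval 94.5% to 95.7%, as if genes were independent). Among genes not called, 67.5% had the same sign. Across the called genes, which are not independent replicates, Pearson's r between the log2 folds of the sets was 0.926, and across all 14139 genes 0.838. The Dasa folds were larger for 3396 of the called genes, and their slope on the dasatinib folds was 1.17. The Dasa set holds 1 wild-type sample and was not tested alone.

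The edgeR interaction test of set and group called 1071 of 14617 genes, 459 with a more positive and 612 with a more negative fold in the Dasa set. Each Dasa fold rests on 1 wild-type sample, whose spread the test takes from the other groups. Of hepatocyte markers 19 of 27 had a more negative fold in the Dasa set. Shares of lists were not tested against one another. G6PC1 fell by 1.79 in the dasatinib set and by 3.08 in the Dasa set. APOB, the apolipoprotein of very low-density lipoprotein, had log2 folds of 0.29 and -0.72, and is named after its value was seen. Its log2 CPM was 12.38 in the 1 wild-type Dasa sample and 11.24 to 11.29 in the other wild-type samples. Of ERK pathway genes 9 of 15, of YAP/TAZ targets 7 of 19 and of SRF targets and actin genes 8 of 18 had a more positive fold in the Dasa set. Of cholesterol synthesis genes 9 of 22, and of mitochondrial transcripts 7 of 13, had a more negative one.

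**Figure D4:**
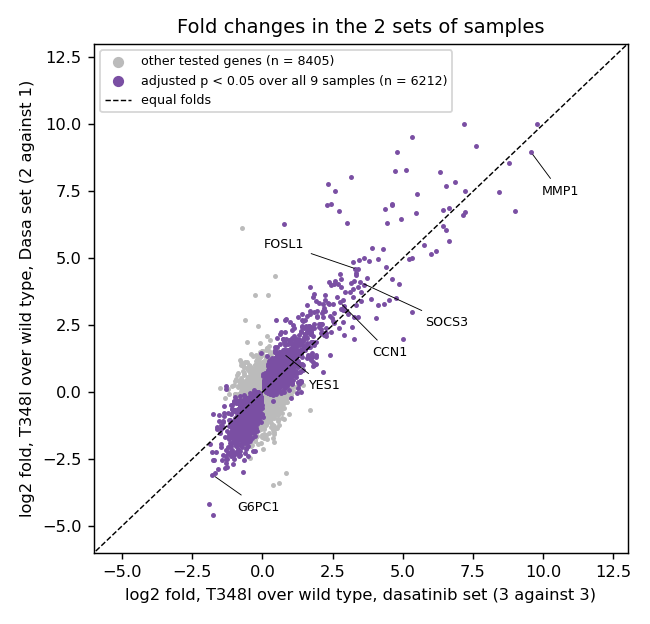
Log2 fold changes of the 14617 tested genes (T348I over wild type) in the dasatinib set (x axis, 3 against 3 samples) and in the Dasa set (y axis, 2 against 1), with the 6212 genes called over 9 samples in purple and a dashed line at equal folds; folds of genes without wild-type reads depend on the prior count. YES1 lies above the line with folds of 1.66 and 2.72, and G6PC1 below it with log2 folds of -1.79 and -3.08.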

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

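The test of YES1 level as an explanation and the split count for lists with an estimated correlation were chosen after the results were seen; the other tests here were set before.

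The T348I effect differed between sets: 1071 genes passed the edgeR test of the difference, which takes the 1 wild-type sample of the Dasa set to vary like samples of the other groups, and the log2 fold of YES1 differed by 0.713. Over the 1071 genes the T348I samples shifted between sets in the direction of the difference by a median of 0.246 (bootstrap 95% interval over genes 0.215 to 0.278). The wild-type samples added a median of 0.188 (0.164 to 0.219) to the difference, and the medians differed by 0.0579 (0.00314 to 0.11). A T348I shift above 0 and above the wild-type shift had been set beforehand as the bound against the single library as the cause, and it was met, but the bound was wrong: genes chosen for the difference shift that way by selection alone, and with 1 wild-type Dasa sample a shift shared by the set is not separable from one of that sample, so the single library cannot be told apart from a T348I effect that differs between sets. For YES1 the wild-type samples held 341 to 362 CPM in the dasatinib set and 368 CPM in the Dasa set. A candidate biological explanation is the higher YES1 level of the T348I samples in the Dasa set, under which folds would be scaled up, and the slope of Dasa folds on dasatinib folds was 1.17 over called genes. YES1 level and set go together, so the level cannot be told apart from other differences between the sets, such as the mitochondrial share of reads. Multimapped reads were 7.14% to 7.99% in the Dasa set and 10.9% to 16.9% in the dasatinib set. Reads in no feature were 9.1% to 9.78% and 5% to 5.8%.

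For the 6212 genes changed, 1 of 100 splits of the 9 samples into 4 and 5, the real one, called as many. The highest of the others called 2585. Of the 99 other splits 97 called 0 genes, since in mixed splits the real group difference stays in the spread within groups. The count therefore shows only that these samples divide more strongly by group than by the other splits run. It cannot exclude a chance difference between cultures, since samples of a group may not be separate cultures. Both other splits that called any gene kept all 4 wild-type samples together with 1 T348I sample. Differences in copy number between the cell lines would make neighbouring genes move together. Windows of 50 neighbouring genes held 7.38% of the variance of the log2 folds of changed genes, capped at 2 in each direction. With genes in random order the mean was 4.88% and the maximum 5.79%. Large folds weigh most in this share, so it cannot decide whether copy number lies behind many of the small changes. Window medians over tested genes ran from -0.266 to 0.133, and 0 of 305 windows lay beyond 0.3. These medians argue against shifts of more than 0.3 over whole windows, while smaller or more local shifts stay open. YES mutation, the higher YES1 transcript level of the T348I samples and clonal differences between the lines are confounded by the groups and remain untested.

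For the 5041 genes of the dasatinib set alone, the 10 splits are too few for a share under 0.05, and the highest other split called 0. For lists at the preset correlation, 4 of 100 splits called as many as the real 18, with 19 the highest other. This share met the bound of under 0.05 that was set beforehand. It does not exclude chance, since the other splits called a median of 12 lists and only 100 of the 126 possible splits were run. With an estimated correlation 1 of 100 splits called as many as the real 9, with 1 the highest other. In the other splits the real group difference stays in the spread within groups and raises the estimated correlation. Few calls could arise there, so this count does not exclude chance.

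The higher YES1 transcript in T348I samples could come from a gain of its chromosome region. The 9 tested genes within 1 Mb of YES1 had a median log2 fold of 0.11 (median absolute deviation 0.13), far below the 0.5 that was set as the least a gain would give. This argues against a gain of the region and leaves unequal expression of the introduced gene open.

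Single samples that stood apart from the others of their group were mostly Yes WT Dasa replicate 1, the 1 wild-type sample of its set. A sample stood apart when its gap to the nearest other sample, as a share of the range of the group, passed Dixon's 95% critical value, which chance passes in about 1 in 20 groups. As the only wild-type sample of its set, this one also carries the difference between the sets, to which that rate does not apply. Its mitochondrial share was 14.4%, against 5.6% to 6.0% in the other wild-type samples. Its mean log2 CPM was higher than in the other wild-type samples for biliary markers (4.511), EGFR ligands and receptors (6.472) and mitochondrial transcripts (12.82). It was lower for G1/S genes (6.179), cholesterol synthesis (6.155), hypoxia and glycolysis (5.593), ATF4 and the unfolded protein response (5.967), p53 targets (4.435) and aryl hydrocarbon receptor targets (4.785). Among single genes, its log2 CPM was higher for G6PC1 (7.626), SLC30A10 (3.488), SLC5A9 (4.717), AMN (5.295), ODC1 (9.537), CDH2 (6.074), FLNA (9.601), OSMR (5.796), AKR1C2 (7.832), AKR1C1 (6.382), MT-ND4 (14.73), COL1A1 (2.738), APOB (12.38), ASGR2 (6.371) and FAM83A (-2.139, from 1 read). It was lower for BAAT (4.06), RAB11FIP4 (6.209), SIK2 (8.057), TM4SF4 (8.171), VIM (6.614), MVK (5.371), INSIG1 (7.221), BHLHE40 (5.363), CYP1A1 (6.851) and ALDH1A1 (10.77). Only genes named in this text were checked, in this sample and the others, so further genes may stand apart.

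In other samples, Yes WT dasatinib replicate 2 had the fewest reads of its group (10464731, or 10.5 M, against 13.7 to 14.1 M). Log2 CPM stood apart for KRT6A (3.496) and FYN (-1.402) in Yes T348I Dasa replicate 2, for CSK (6.534) in Yes T348I dasatinib replicate 1, for LBP (0.7724) and IL24 (-2.191, from 1 read) in Yes WT dasatinib replicate 3, and for BCL2A1 (-1.795, from 2 reads) in Yes WT dasatinib replicate 1.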

How the results depend on the processing

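The YES1 fold kept its direction and its call under every alternative run, with a log2 fold from 0.7376 to 1.082 (0.7376 to 1.003 with 1 sample left out). Gene calls kept within 1.5 times of 6212 (3029 higher, 3183 lower) except with a 1.5-fold minimum, which left 1366 (708 and 658) because fewer genes can pass, and without the set term, which left 2350 (1234 and 1116), with 3860 calls lost and 2 signs changed; the cause was not tested. With 1 sample left out, 5131 to 5925 genes were called, the fewest without Yes WT Dasa replicate 1. Lists called numbered 16 to 19 over the scalings, filters, models and samples left out, 27 with fry and 9 with an estimated correlation, whose larger spread is part of that test. Same-sign agreement between sets was 95.2% under the other filter and scaling and 96.0% with calls at an unadjusted p under 0.01, a stricter choice that kept fewer genes. The interaction count lay between 1067 and 1083 under other scalings, filters and strand counts, alternatives chosen after seeing the data, and between 786 and 1064 with 1 sample left out; it could not be fitted without Yes WT Dasa replicate 1. Replicate numbers did not pair the samples: same-numbered samples of the dasatinib set had correlations of -0.0077, -0.076 and 0.0033. The replicate block gave 5372 genes (2659 higher, 2713 lower), 5288 of them among the 6212, and 16 lists. DESeq2 has no list test, and limma-voom was run in its place. Values not called that changed sign were LYN (-0.009593 with upper quartile, -0.004941 with no filter, -0.0381 without the set term, -0.00765 with the block, -0.00198 in the dasatinib set), LYZ (-0.019 without the set term), FYN (0.03673 with the block), and list medians of biliary markers (0.0363 without the set term, 0.0632 with the block, 0.112 in the dasatinib set, 0.00265 with limma-voom), ATF4 and the unfolded protein response (-0.0341 without the set term), fatty acid synthesis (0.026 in the dasatinib set), epithelial markers (0.13) and fibroblast markers (-0.121), both with no filter. With 1 sample left out they ranged from -0.2895 to 0.05376 (FYN), -0.005331 to 0.01887 (LYN), -0.003863 to 0.1629 (LYZ), -0.0716 to 0.111 (biliary), -0.0222 to 0.0259 (fatty acid) and -0.0164 to 0.0384 (ATF4). The cause was not tested. Apart from the samples left out, 1423 values of named genes kept direction and side, 43 lost the call, 2 gained it and 7 changed sign. Depth limits the genes with few wild-type reads, whose ratios have wide intervals. In simulated data at this depth 52% of 1.2-fold changes were found. Genes of low mean count were left out of the changed ones, and far fewer genes were changed than were called in the real data.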

Other observations

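Gene families grouped by the stem of their symbols were tested after the data had been seen. Of 471 families with at least 5 tested genes, camera called 16 at the preset correlation, and each of these calls was lost with an estimated correlation. Genes with symbols in KRT, most of them keratins of the intermediate filaments of epithelium, rose in 17 of 21 cases (median 1.22, camera adjusted p = 1.03e-12, and adjusted p = 0.435 with an estimated correlation). Besides KRT6A, KRT19, KRT18 and KRT8 these included KRT15, a keratin of basal epithelium, which rose by 4.49, from 0.559 ± 0.439 CPM (SD, n = 4) to 14.4 ± 5.45 CPM (SD, n = 5). Some members are pseudogenes that share reads with their parents, and KRT10-AS1 is an antisense gene. Genes with symbols in SERPINB, mostly intracellular serpins, rose in 5 of 6 cases (adjusted p = 0.711 with an estimated correlation). Aldehyde dehydrogenases fell in 10 of 14 cases and rose in 2 (median -0.35, camera adjusted p = 0.0117, and adjusted p = 0.984 with an estimated correlation), and ALDH1A1, which makes retinoic acid, fell by 0.95, from 2260 ± 338 CPM (SD, n = 4) to 1120 ± 305 CPM (SD, n = 5). The counts of these 3 families were the same under the other scalings.

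Genes with symbols in RPL, most of them ribosomal protein genes and their pseudogenes, rose in 55 of 120 cases (median 0.26, camera adjusted p = 0.0016, and adjusted p = 0.984 with an estimated correlation). Those in RPS, which also include S6 kinase genes such as RPS6KA4, rose in 36 of 71 cases and fell in 4 (median 0.23, camera adjusted p = 0.0435, and adjusted p = 0.984 with an estimated correlation). With upper quartile scaling 54 of the RPL genes rose.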
